A study of Homo sapiens with 12 samples.

How the data were processed

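Gene expression was measured by RNA sequencing in 12 libraries from 3 human leukemia cell lines, with 4 libraries per line. K562 is an established line from chronic myeloid leukemia in blast crisis that carries the BCR-ABL fusion. K/VP.5 is a clonal subline of K562 that resists etoposide, a drug that traps topoisomerase II on cut DNA. K/VP.5/edit-3, called edit-3 here, is a K/VP.5 clone in which Cas9, a guide RNA and a single-stranded repair template altered the 5′ splice site at the end of exon 19 of TOP2A, the gene of topoisomerase IIα, so that the splicing machinery would recognise it better. Each library was assigned to its line by its source name, and replicate numbers came from the titles. The free-text description names the parental cells for every library and conflicts with the source names, so it was not used. Per the labels, the cells were kept in medium to which 0.5 µM etoposide was added every other week. That sentence covers all 3 lines together and leaves open whether K562 also received the drug. The labels do not say whether the 4 libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

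The authors deposited 1 table of raw read counts per gene, as whole numbers that were not normalized, for 58395 Ensembl gene IDs with a symbol and a biotype for each. Per the submitters' processing notes, HISAT2 2.1.0, Subread 1.5.1 and its counting program featureCounts were used with the GRCh38 build. The annotation release, the strand setting, and how reads with several matches were counted are not given in the sources used here. Per the labels' protocols, column-purified RNA was treated with DNase and made into libraries by a standard Illumina procedure. Whether poly(A) RNA was selected or ribosomal RNA removed is not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene could not be separated, and antisense genes were left out of the named genes. Genes with near-identical copies, such as histone genes, HLA-B and HLA-C, GYPB and GYPE, IFITM2 and IFITM3, ABCC6, PRSS2, TRBC1, clustered zinc finger and olfactory receptor genes and small nuclear RNA genes, can share reads with their copies, so their values are uncertain. A count per gene sums over its transcripts. The TOP2A values therefore do not separate transcripts that keep intron 19 from those that remove it, and the share of intron 19 retention was not measured here.

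Library totals ran from 25.3 M reads (K562 replicate 4) to 37.1 M (K/VP.5 replicate 4), with a median of 29.6 M. Levels are given as CPM, read counts scaled to the size of the library, computed here from the deposited counts with TMM-scaled library sizes, as the mean ± SD of the 4 libraries. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with too few reads were removed by filterByExpr, which left 18286 genes holding 99.89% of all reads. Negative binomial models with 1 coefficient per line were fitted to all 12 libraries, and 3 comparisons were tested with edgeR's robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as changed. Log2 fold changes come with a standard error (SE), computed as their size divided by the square root of the quasi-likelihood F statistic. Where 1 line had 0 reads, the fold was computed against a floor of 3 reads over the 4 libraries and is a lower bound. Where it had 1 to 3 reads, the reads are given, and any ratio printed has an exact 95% Poisson interval. Both cover counting error only, and for such genes the library that holds the reads can move the fold by more than 1.5 times.

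Libraries of a line were compared in pairs over genes with at least 20 reads. The chi-square statistic per degree of freedom was between 6.72 and 68, so no library looked like a second copy of another. The titles give the same replicate numbers, 1 to 4, in each line. Deviations from the line means correlated at 0.31, 0.15, 0.14 and 0.51 between same-numbered K562 and K/VP.5 libraries, and each correlated best with its own number. These numbers were taken to pair the K562 and K/VP.5 libraries, from the data and not from the labels. With the replicate number as a block, 7681 genes changed in K/VP.5 versus K562 against 6688 without it. For edit-3 the correlations ran from -0.11 to 0.47. Edit-3 replicates 1 and 4 correlated best with their own number in both other lines (0.36 and 0.31 with K/VP.5, 0.47 and 0.31 with K562). Edit-3 replicates 2 and 3 did not, so the edit-3 libraries were not taken as paired, although part of the spread seems shared.

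Before the data were examined, 31 gene lists, the tests, the rule for named genes and most alternatives were fixed. Of the 1008 symbols in the lists, 1003 matched a gene in the table. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the 31 lists. The lists described below hold topoisomerases and tyrosyl-DNA phosphodiesterases, genes around TOP2A on 17q21.2, drug efflux transporters, repair and checkpoint genes of double-strand breaks, apoptosis regulators, replication-dependent histones, erythroid, megakaryocyte, lymphoid and granulocyte or monocyte genes, glutathione genes and other targets of the transcription factor NRF2, antigen presentation, interferon response, splice site recognition factors, adhesion and matrix genes, nuclear genes of oxidative phosphorylation and abundant RNAs without poly(A) tails. The genes named are TOP2A and TOP2B, the 10 largest changes in each direction per comparison, up to 4 members with the lowest adjusted p in each list described, and the 6 largest K/VP.5 changes in each overlap. The 10 largest had to have an adjusted p under 0.05, a mean of at least 5 CPM in the higher line and no overlap between the libraries of both lines. Some genes that this rule picks are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

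The overlap of comparisons that share libraries was measured with the 4 shared libraries split 2 and 2, in all 6 ways, and set beside simulated groups without any change, which were fitted without the split. Gene positions and the TOP2A exons are from GENCODE 29 on GRCh38, which held 58275 of the IDs. Runs of shifted neighbours were sought among 9764 protein-coding genes with a mean of at least 5 CPM, as a running median over 21 genes beyond 0.3 on the log2 scale for at least 10 genes. This search was added after the data were seen.

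The scripts were tested on simulated counts with 200 genes changed by known folds. edgeR called 69% of the 2-fold and 89% of the 4-fold changes for K/VP.5 versus K562. It also called 13 unchanged genes among 17878 genes tested, changed ones included. For edit-3 versus K/VP.5 it called 61% and 90%, with 11 unchanged genes called among 17913 tested. For edit-3 versus K562 it called 62% and 91%, with 5 among 17903. No changed gene was called in the wrong direction, and 97 to 99 of 100 genes of a simulated shifted region were found. None of 30 unshifted lists passed. The genes were simulated without correlation between them, so this does not check the list tests where genes move together. The alternatives were DESeq2's size factors, DESeq2's Wald test, no filter, a stricter filter of a mean of 1 CPM, fits of only the 2 groups compared, the replicate block, camera with an estimated correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were the block within 2 groups, the main axis of spread within lines as a covariate, leaving out both libraries at the ends of that axis, list tests without each library, and other settings of the run search. Variants, transcript isoforms and sex-linked marker genes were not analysed here.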

Results

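RNA of K562, K/VP.5 and edit-3 cells was sequenced in 12 libraries, 4 per line. Library totals lay between 25.3 M and 37.1 M reads, of which 95.2% to 96.2% fell in protein-coding genes and 0.712% to 1.22% in mitochondrial genes. Log CPM values correlated at 0.979 to 0.994 between libraries of the same line. The correlation was 0.956 to 0.968 between K/VP.5 and edit-3, 0.935 to 0.948 between K/VP.5 and K562, and 0.925 to 0.94 between edit-3 and K562. The first principal component held 55.1% of the variance and the second 24%. The main axis of spread within lines held 39.8% of that spread, with K562 replicate 4 at 50.4 and edit-3 replicate 1 at -38.8 at its ends.

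K/VP.5 was compared with K562 to describe how the etoposide-resistant subline differs from its parent, above all in topoisomerase II. TOP2A, the main nuclear target of etoposide (ENSG00000131747, chromosome 17, 40388516 to 40417950, minus strand), stood at 519 ± 25.8 CPM in K562 and 359 ± 14.5 CPM in K/VP.5 (SD, n = 4), a log2 fold change of -0.53 (SE 0.065, adjusted p = 1.2e-05). TOP2B, the gene of the second topoisomerase II isoform on chromosome 3, fell from 336 ± 35.5 to 255 ± 10.3 CPM, or by 0.39 on the log2 scale (SE 0.080, adjusted p = 0.0012), and its 20 measured neighbours had a median log2 fold change of -0.30, 16 of them with the same sign. ABCC1, which encodes the drug efflux pump MRP1, rose from 206 ± 15.9 to 353 ± 22.6 CPM (log2 fold change 0.77, SE 0.071, adjusted p = 7e-07). ABCG2, the pump BCRP, rose from 0.392 ± 0.20 to 3.81 ± 0.75 CPM (log2 fold change 3.25, SE 0.33, adjusted p = 1.7e-06). In all, 6688 of 18286 genes changed, 3349 higher and 3339 lower in K/VP.5, and 2457 changed at least 2-fold, 1500 higher and 957 lower.

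**Figure D1:**
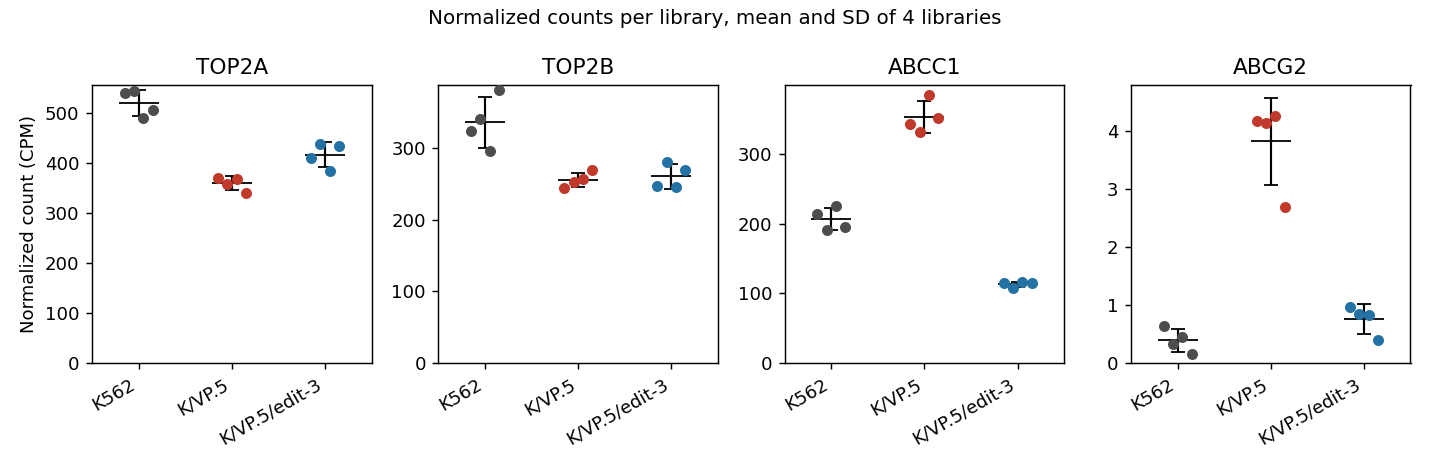
Normalized counts (CPM, vertical axes from 0) of TOP2A, TOP2B, ABCC1 and ABCG2 in each library of the 3 lines; points are libraries, and horizontal bars with whiskers are the mean ± SD of 4 libraries. TOP2A means were 519 CPM in K562, 359 in K/VP.5 and 416 in edit-3, while ABCC1 means were 206, 353 and 113.

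The genes with the largest rises in K/VP.5 had low counts in K562. LIN28A, an RNA-binding protein that blocks maturation of let-7 microRNAs, went from 0.385 ± 0.18 to 166 ± 16 CPM (log2 fold change 8.72, SE 0.20, adjusted p = 2.8e-13). HAND2, a transcription factor of heart and limb development, reached 16.8 ± 0.65 CPM against 2 reads over the 4 K562 libraries, a ratio of 950 (95% interval 263 to 7850). TFAP2B, an AP-2 family transcription factor, reached 20.9 ± 3.95 CPM against 1 read, a ratio of 2340 (419 to 92400), with a fitted log2 fold change of 10.7 that was 12.3 without K562 replicate 2. CLDN11, a tight junction protein, rose from 0.122 ± 0.10 to 40.3 ± 3.27 CPM (log2 fold change 8.30, and 9.03 without K562 replicate 2). LINC01606 had 0 reads in K562 and was at least 236-fold higher in K/VP.5. The amino acid transporter SLC7A2, ZNF850, the metalloprotease ADAMTS1 and the translation termination factor GSPT2 had 2 or 3 reads in K562 and between 8.42 and 18.9 CPM in K/VP.5, and UGT8 rose to 16.4 ± 3.06 CPM.

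The largest falls in K/VP.5, ranked by fitted log2 fold change under the rule for named genes, were led by a pair of neighbouring histone genes. HIST1H3F, a histone H3 gene, went from 176 ± 15.8 to 0.21 ± 0.14 CPM and HIST1H2BH, a histone H2B gene, from 106 ± 12.5 to 0.115 ± 0.080 CPM, with log2 fold changes of -9.73 and -9.78 (SE 0.24 and 0.25, adjusted p = 1.2e-12 for both). KCNMA1, a calcium-activated potassium channel, dropped from 38.2 ± 8.35 to 0.0796 ± 0.024 CPM (log2 fold change -8.86). ZPLD1, ZFAND4, IGSF11 and TMEM108 each had 1 read over the 4 K/VP.5 libraries against means of 5.18 to 7.76 CPM in K562. The adhesion receptor gene ADGRA3 had 2 reads against 9.38 ± 2.22 CPM. The olfactory receptor genes OR52D1 and OR51I2, on chromosome 11, had 2 and 4 reads against 6.14 ± 1.1 and 8.05 ± 1.34 CPM.

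Among 8 topoisomerases and tyrosyl-DNA phosphodiesterases, 1 rose (2 when adjusted over the list alone), 4 fell (4 when adjusted over the list alone) and 3 did not pass, with no shift of the list as a set (camera adjusted p = 0.84). TOP1MT, the mitochondrial topoisomerase I, rose by 0.55 on the log2 scale (adjusted p = 0.00031), and TDP2, which releases trapped topoisomerase II from DNA, fell by 0.27 (adjusted p = 0.028), a call that ended without K562 replicate 1 or 3 or K/VP.5 replicate 2 or 4 (highest adjusted p = 0.097) and without a filter (adjusted p = 0.063). Of 15 genes around TOP2A on 17q21.2, 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.84). RARA, the retinoic acid receptor α gene, had a log2 fold change of -0.67 and RAPGEFL1 of -0.76, while CDC6, a replication licensing factor, rose by 0.32 (adjusted p = 0.00034, 0.012 and 0.010). The 20 measured neighbours of TOP2A had a median log2 fold change of -0.075. Of 9 drug efflux transporters tested, 5 rose and 1 fell (the same counts when adjusted over the list alone), with camera adjusted p = 0.13. Beside ABCC1 and ABCG2, the transporters ABCC4 and ABCC6 rose by 0.47 and 1.33 (adjusted p = 2.6e-05 and 0.00033). ABCB1, the P-glycoprotein gene and a member too low to be tested, had 0 reads in all 12 libraries and is named here after its value was seen.

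The glycophorin genes GYPB and GYPE, which share sequence, rose from 1.54 ± 0.29 and 3.67 ± 1.05 CPM to 41.6 ± 4.98 and 74.3 ± 10.4 CPM. XK, a red cell membrane transporter gene, rose from 10.1 ± 1.64 to 142 ± 5.76 CPM (log2 fold change 3.81, SE 0.13, adjusted p = 1.7e-11). The 49 erythroid genes moved in both directions, with 14 higher, 10 lower and 25 not passing (14 and 11 when adjusted over the list alone, camera adjusted p = 0.21). Of 17 megakaryocyte and platelet genes, 6 rose and 6 fell (6 and 7 when adjusted over the list alone, camera adjusted p = 0.21), with a median log2 fold change of -0.033 and a mean of 0.67. P2RY1, a platelet ADP receptor, fell from 74.5 ± 4.32 to 6.09 ± 0.40 CPM, whereas the tetraspanin gene CD9, the matrix gene SPARC and LTBP1 rose by 6.81 (7.63 without K562 replicate 2), 3.61 and 2.28 on the log2 scale.

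The 35 replication-dependent histones were lower as a set in K/VP.5, with 6 higher, 15 lower and 14 not passing (6 and 16 when adjusted over the list alone). Their median log2 fold change was -0.22 (camera adjusted p = 3.1e-05, adjusted p = 0.99 with an estimated correlation). Without HIST1H3F and HIST1H2BH the call ended (adjusted p = 0.17). HIST1H4D and HIST1H4A, both histone H4 genes, fell by 1.46 and 0.72 (adjusted p = 7.7e-08 and 7.2e-06). Among 6 abundant RNAs without poly(A) tails, whose yield can vary with RNA selection, 1 rose and 2 fell, or 1 and 3 when adjusted over the list alone (camera adjusted p = 0.72). RN7SL2, the RNA of the signal recognition particle, fell from 8900 ± 496 to 5770 ± 1010 CPM (adjusted p = 0.00054). RNU4-2 and RNU5A-1 lay close to the threshold, with log2 fold changes of -0.71 and 0.84 (adjusted p = 0.050 and 0.046; with the replicate block, RNU5A-1 had 0.82 and adjusted p = 0.059), and RNU1-1 did not pass at -0.75 (adjusted p = 0.054). The RNU4-2 call ended in every fit without 1 library but those without K562 replicate 1 or 4 (highest adjusted p = 0.20), and the RNU5A-1 call in every one but those without K562 replicate 2 or K/VP.5 replicate 2 (highest adjusted p = 0.16), while RNU1-1 passed without K562 replicate 3 (adjusted p = 0.021), with DESeq2 (adjusted p = 0.016) and in fits of only these 2 lines (adjusted p = 0.047, or 0.015 with the replicate block). Without a filter the RNU4-2 and RNU5A-1 calls ended too (adjusted p = 0.084 and 0.066), as did RNU4-2 with DESeq2's size factors or the stricter filter (adjusted p = 0.050 and 0.054) and RNU5A-1 with DESeq2 (adjusted p = 0.072).

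Of 33 glutathione genes and other NRF2 targets, 3 rose and 13 fell (3 and 14 when adjusted over the list alone, camera adjusted p = 0.060). TALDO1, an enzyme of the pentose phosphate pathway, had a log2 fold change of -1.03, the glutathione transferase gene MGST1 of -1.97 and AKR1C3 of -1.83 (adjusted p between 3.3e-08 and 6.3e-07). Of 36 genes of double-strand break repair and checkpoints, 8 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.94). ATR, a checkpoint kinase, and LIG3, a DNA ligase, fell by 0.88 and 0.56, and the helicase gene WRN and BRCA2 rose by 0.40 and 0.68. Of 30 apoptosis regulators, 6 rose and 11 fell (6 and 12 when adjusted over the list alone, camera adjusted p = 0.72), with a median of -0.029 and a mean of 0.068. BCL2 and BAX fell by 0.84 and 0.56, and BCL2L11 and HRK, both encoding pro-apoptotic proteins, rose by 0.71 and 3.59. Of 13 antigen presentation genes, 4 rose and 4 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.21). HLA-C, a class I heavy chain gene, rose from 0.101 ± 0.096 to 7.83 ± 0.27 CPM. HLA-B had 3 reads in K562 and 1.39 ± 0.22 CPM in K/VP.5 (ratio 52.7, interval 17.8 to 258, fitted log2 fold change 5.50 and 6.50 without K562 replicate 4), and CIITA and TAP1 rose by 1.02 and 0.81.

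The histone list was 1 of 31 that passed in K/VP.5 versus K562, none passed with an estimated correlation, and 2 passed with the replicate block. Counts of passing lists were as large in most other groupings of the same libraries, so they do not separate the lines from chance. The 20 measured neighbours of ABCC1 had a median log2 fold change of 0.46, 13 of them with the same sign. ABCC1 lies in a run of 30 genes at 10.74 to 18.56 Mb of chromosome 16. The run was found by the shared shift of its genes and had a median of 0.84. Inside all runs of this comparison 81.4% of genes changed, against 34.2% of the searched genes outside. Whether ABCC4, ABCC6, ATR, LIG3, BRCA2, TALDO1, MGST1 and AKR1C3, named above, lie in runs was not examined. A regional shift thus stays open for these genes.

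**Figure D2:**
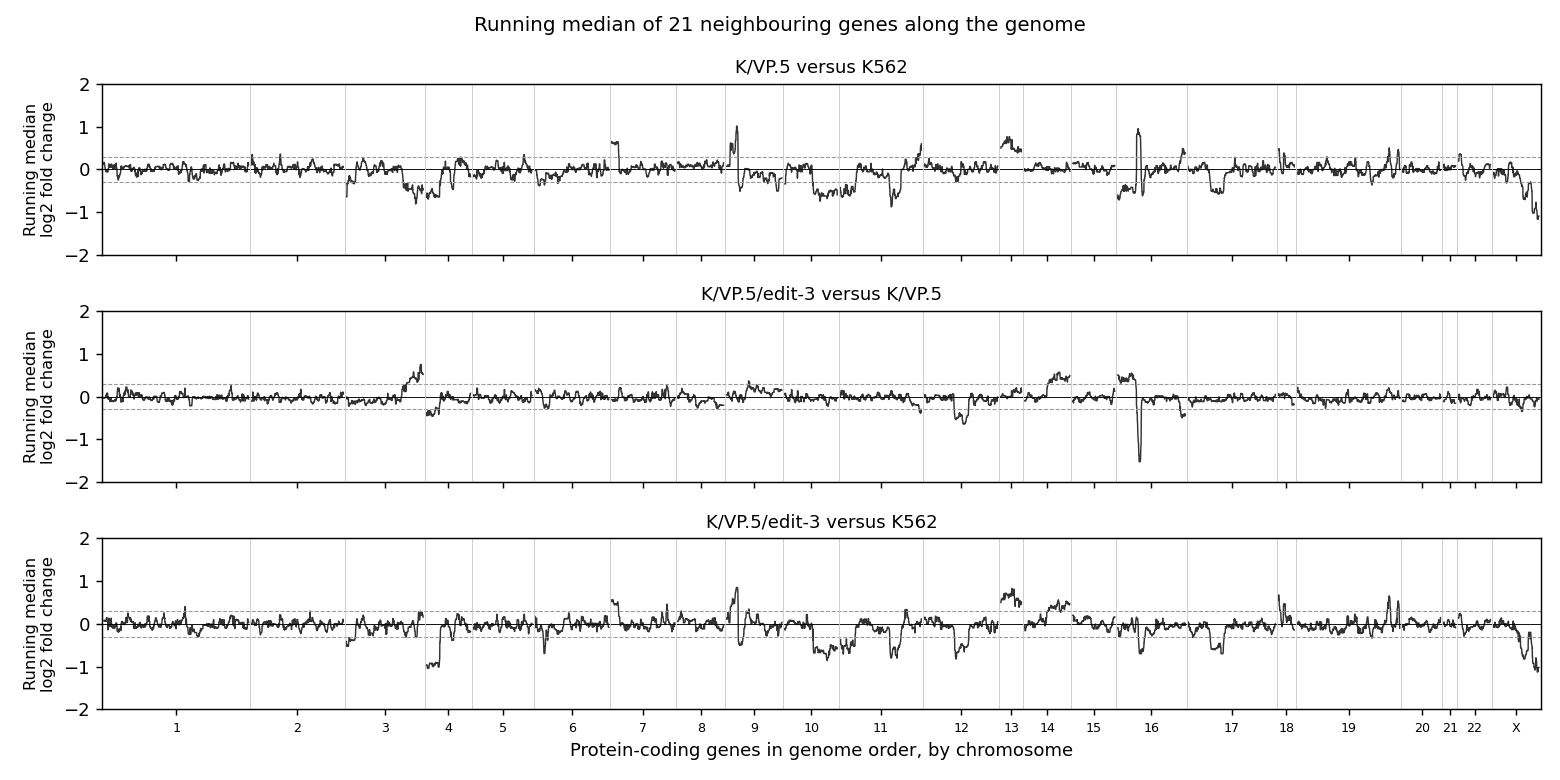
Running median of the log2 fold change over 21 neighbouring protein-coding genes (vertical axes) in genome order by chromosome (horizontal axis) for the 3 comparisons; dashed lines mark 0.3 and -0.3, grey lines separate chromosomes, and only genes with a full window are drawn. The stretch around ABCC1 on chromosome 16 was higher in K/VP.5 than in K562 (median 0.84 over 30 genes) and lower in edit-3 than in K/VP.5 (-1.20 over 30 genes).

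Edit-3 was compared with K/VP.5 to see what differed after the splice site of TOP2A had been altered. The edited site lies between exon 19 (40404152 to 40404273 on chromosome 17), 1 of 35 exons, and intron 19 (40403055 to 40404151, 1097 bp), and the exon ends in GAG. TOP2A stood at 416 ± 25.1 CPM in edit-3 and 359 ± 14.5 CPM in K/VP.5 (SD, n = 4), a log2 fold change of 0.21 (SE 0.065, adjusted p = 0.027). This call is weak: it ended in 6 of 8 fits without 1 library, each of edit-3 replicates 2 and 4 and of the 4 K/VP.5 libraries (log2 0.17 to 0.22, highest adjusted p = 0.11), without a filter (0.20, adjusted p = 0.14) and with only these 2 lines in the fit (0.20, adjusted p = 0.051). TOP2B differed by less than the spread between libraries, at 261 ± 17.7 against 255 ± 10.3 CPM (log2 fold change 0.03, SE 0.080, adjusted p = 0.83). Both efflux pumps named above were lower in edit-3, ABCC1 at 113 ± 3.62 CPM (log2 fold change -1.64, SE 0.073, adjusted p = 5.8e-10) and ABCG2 at 0.756 ± 0.25 CPM (-2.33, SE 0.30, adjusted p = 3.9e-05).

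In all, 4309 genes changed between edit-3 and K/VP.5, 2368 higher and 1941 lower, and 1522 changed at least 2-fold, 941 higher and 581 lower. Edit-3 is 1 clone, so the splice site edit and other differences of the clone cannot be separated in these data. Among the largest falls, LIN28A fell from 166 ± 16 to 0.434 ± 0.12 CPM (log2 fold change -8.56, SE 0.19, adjusted p = 1.9e-12), TFAP2B to 0.0503 ± 0.022 CPM, SLC7A2 to 0.0994 ± 0.055 CPM and ADAMTS1 to 0.0323 ± 0.065 CPM, with all 4 of its reads in edit-3 replicate 1 (log2 fold change -8.72, and -11.9 without that library). LINC01606 had 1 read in edit-3 (ratio 764, interval 137 to 30200, fitted log2 fold change -8.98 and -10.6 without edit-3 replicate 2). PLOD2, a lysyl hydroxylase of collagen, fell from 28.1 ± 3.24 to 0.073 ± 0.054 CPM, PREX2, a Rac exchange factor, from 18.9 ± 2.35 to 0.0674 ± 0.032 CPM, and the adhesion receptor gene ADGRL3 from 27.5 ± 1.85 to 0.178 ± 0.099 CPM. The potassium channel gene KCNQ5 and the actin-bundling gene PLS3 had 3 reads each in edit-3 against 9.79 ± 1.76 and 5.16 ± 0.16 CPM.

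Of the 10 largest rises in edit-3, 4 were genes close together on chromosome 7, between the start of PRSS2 at 142760398 and the end of TRPV6 at 142885762. EPHB6, an Eph receptor without kinase activity, rose from 2.86 ± 0.77 to 327 ± 121 CPM (log2 fold change 6.83, SE 0.51, adjusted p = 3.2e-06), and the calcium channel gene TRPV6 from 0.0428 ± 0.045 to 14.7 ± 7.72 CPM. PRSS2, a trypsinogen gene, and TRBC1, a constant segment of the T cell receptor β chain, had 3 reads each in K/VP.5 and 9.41 ± 6.68 and 5.0 ± 2.82 CPM in edit-3, ratios of 405 (138 to 1970) and 216 (73.7 to 1050). Their fitted log2 fold changes were 8.42 and 7.51, and 9.25 without K/VP.5 replicate 4 for PRSS2 and 8.46 without K/VP.5 replicate 2 for TRBC1. NNMT, a nicotinamide methyltransferase, rose to 9.78 ± 2.20 CPM and SH3BP4 to 19.1 ± 1.12 CPM (log2 fold changes 7.59 and 6.0). LCP2, the adaptor SLP-76 of blood cells, MS4A3, a marker of myeloid progenitors, MLC1 and the cadherin gene CDH18 rose by 6.33, 5.46, 6.50 and 5.58 on the log2 scale.

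Interferon response genes were higher as a set in edit-3, with 9 of 22 higher, 2 lower and 11 not passing (11 and 3 when adjusted over the list alone). Their median log2 fold change was 0.50 (camera adjusted p = 1.5e-07, adjusted p = 0.11 with an estimated correlation). IFITM3, a restriction factor against viral entry, rose from 3.45 ± 0.49 to 48.1 ± 3.43 CPM (log2 fold change 3.80, SE 0.12, adjusted p = 2.4e-11), OAS3, a sensor of double-stranded RNA, from 0.753 ± 0.15 to 11.4 ± 1.08 CPM and IFIH1, the RNA sensor MDA5, from 0.722 ± 0.16 to 8.01 ± 1.02 CPM. Antigen presentation genes were higher too, with 9 of 13 higher, 1 lower and 3 not passing, also when adjusted over the list alone (median 0.77, camera adjusted p = 9.2e-06, adjusted p = 0.036 with an estimated correlation). Both lists hold TAP1, PSMB8 and PSMB9, so their calls are not fully separate results. TAP1 and TAP2, the peptide transporters of class I loading, rose from 2.55 ± 0.23 to 19.2 ± 2.28 CPM and from 14.5 ± 1.46 to 29.3 ± 3.18 CPM. PSMB9, an immunoproteasome subunit, rose by 3.12 and B2M, the class I light chain, by 0.77 on the log2 scale (adjusted p = 1.1e-05 and 3.1e-05). Of the 13 antigen presentation genes, 8 lie on chromosome 6, and the 5 others did not pass as a set (adjusted p = 0.39). Granulocyte and monocyte genes and lymphoid genes had median log2 fold changes of 1.10 and 0.58 in the same comparison.

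Of 35 replication-dependent histones, 18 fell, none rose and 17 did not pass (21 lower when adjusted over the list alone), with a median log2 fold change of -0.30 (camera adjusted p = 4.7e-05, adjusted p = 0.90 with an estimated correlation). HIST1H2AI fell from 237 ± 12.6 to 129 ± 21.6 CPM (log2 fold change -0.87, SE 0.10, adjusted p = 1.5e-05), and HIST1H2BL, HIST1H2AC and HIST1H2BC, further H2A and H2B genes, fell by 0.90, 0.55 and 0.61. HIST1H3F and HIST1H2BH stayed near 0 in edit-3, at 0.232 ± 0.066 and 0.16 ± 0.096 CPM. Of 9 drug efflux transporters, 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.10). ABCA3, a lipid transporter gene, rose by 0.53 and ABCC6 fell by 1.32 (adjusted p = 0.00019 and 0.00058). The 20 measured neighbours of ABCC1 had a median log2 fold change of -1.30, 17 of them with the same sign. A run of 30 genes at 10.94 to 18.80 Mb of chromosome 16, found by their shared shift, had a median of -1.20. Inside all runs of this comparison 72% of genes changed, against 23.4% of the searched genes outside. Whether ABCA3 and ABCC6 lie in runs was not examined, so a regional shift stays open for both.

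Of 8 topoisomerases and tyrosyl-DNA phosphodiesterases, 2 rose, 1 fell and 5 did not pass, also when adjusted over the list alone, with a median of -0.011 and camera adjusted p = 0.90. TDP1, which releases trapped topoisomerase I, rose by 0.40 (adjusted p = 0.00072). TOP1MT fell by 0.29 (adjusted p = 0.038), a call that ended without edit-3 replicate 2 or 4 or K/VP.5 replicate 1, 2 or 3 (highest adjusted p = 0.11). TOP3B did not pass at -0.27 (adjusted p = 0.27) but passed without edit-3 replicate 3 (adjusted p = 0.036). Of 15 genes around TOP2A, 3 rose and none fell, also when adjusted over the list alone (median -0.077, mean 0.35, camera adjusted p = 0.89). The chemokine receptor gene CCR7 rose from 0.198 ± 0.071 to 2.02 ± 0.72 CPM and IGFBP4, which binds insulin-like growth factors, from 31.1 ± 12.9 to 145 ± 56.1 CPM, and NR1D1 did not pass at -0.20 (adjusted p = 0.24). Of 61 splice site recognition factors, none rose and 5 fell, 2 of them when adjusted over the list alone (camera adjusted p = 0.19). SNRNP70, a protein of the U1 particle that binds 5′ splice sites, fell from 329 ± 7.75 to 241 ± 31.1 CPM (log2 fold change -0.45, SE 0.087, adjusted p = 0.0013), and RBFOX2 fell by 0.32 (adjusted p = 0.0051). PTBP2 and PRPF3 had log2 fold changes of -0.36 and -0.36 (adjusted p = 0.030 and 0.040), calls that ended without edit-3 replicate 2 or 3 or K/VP.5 replicate 1 or 2 and, for PRPF3, also without edit-3 replicate 4 or K/VP.5 replicate 3 (highest adjusted p = 0.078 and 0.10).

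Of 36 double-strand break repair and checkpoint genes, 4 rose and 3 fell, also when adjusted over the list alone (median -0.012, mean 0.025, camera adjusted p = 0.89). The ubiquitin ligase gene RNF168, TP53BP1 and LIG4, all of break repair, rose by 0.51, 0.29 and 0.49, and the checkpoint kinase gene CHEK2 fell by 0.48. Whether these genes or TDP1 lie in runs of shifted neighbours was not examined, so a regional shift stays open for each of them. Of 30 apoptosis regulators, 9 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.094). BCL2L1, the gene of the anti-apoptotic BCL-XL, rose from 62.1 ± 7.55 to 125 ± 15.6 CPM, BIRC3 rose by 3.03, and CASP10 fell by 0.90. Of 49 erythroid genes, 11 rose and 11 fell (13 and 11 when adjusted over the list alone, camera adjusted p = 0.81). CA2, a carbonic anhydrase gene, fell from 24.8 ± 1.39 to 2.75 ± 0.63 CPM, RHAG from 1010 ± 78.3 to 491 ± 47 CPM and GYPB by 0.95, and SLC4A1, the band 3 anion exchanger, rose by 1.92.

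Markers of other blood lineages moved in both directions. Of 14 lymphoid genes, 4 rose and 1 fell (5 and 1 when adjusted over the list alone, camera adjusted p = 0.27), with RAG1, TRBC1 and CD3D higher and EBF1 lower. CD3D, a T cell receptor subunit, stood at 35.3 ± 12.8 CPM in edit-3, 10.7 ± 3.46 CPM in K/VP.5 and 50 ± 18.6 CPM in K562. Of 13 granulocyte and monocyte genes, 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.89). The Fc receptor gene FCGR2A rose from 14.7 ± 6.42 to 104 ± 40.8 CPM and AZU1 by 1.70, while VCAN and CEBPD fell by 3.72 and 0.75. Of 34 adhesion, cytoskeleton and matrix genes, 12 rose and 7 fell (14 and 8 when adjusted over the list alone, camera adjusted p = 0.082). CD44, a hyaluronan receptor, rose from 0.0949 ± 0.032 to 3.38 ± 1.54 CPM, and COL4A2, ANXA2 and S100A6 rose by 2.38, 0.74 and 4.72 (adjusted p = 4.5e-08, 2e-06 and 3.4e-06).

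Of 31 lists, 3 passed in edit-3 versus K/VP.5 and 1 of them with an estimated correlation. With the replicate block 7 passed, and leaving out 1 library gave 3 to 6. Counts of passing lists were again as large in most other groupings of the libraries. With the within-line axis as a covariate, chosen after seeing the data, 6587 genes changed instead of 4309.

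Edit-3 was then compared with K562 to see which differences from the parental line were present in the edited clone. TOP2A and TOP2B were both lower than in K562, with log2 fold changes of -0.32 (416 ± 25.1 against 519 ± 25.8 CPM, SE 0.065, adjusted p = 0.0010) and -0.36 (261 ± 17.7 against 336 ± 35.5 CPM, SE 0.080, adjusted p = 0.0019). The 20 measured neighbours of TOP2B had a median of -0.39, 16 of them with the same sign. ABCC1 was lower than in K562 by a log2 fold change of -0.87 (SE 0.072, adjusted p = 1.8e-07). Its 20 measured neighbours had a median of -0.62, 20 of them with the same sign, and ABCC1 lies in a run of shifted genes here too. Altogether 7166 genes changed, 3762 higher and 3404 lower, and 2739 changed at least 2-fold, 1837 higher and 902 lower. Among the largest rises, ZNF91, which represses retrotransposons, went from 4 reads to 23.4 ± 3.12 CPM (log2 fold change 9.21), and ZNF329, ZNF548 and ZNF736 had 1 or 2 reads in K562 and 6.47 to 9.64 CPM in edit-3. ZNF527, ZC4H2 and the pseudogene CENPIP1 had 0 reads in K562 and were at least 208-fold, 201-fold and 187-fold higher. ADGRG6, SH3BP4 and the kinesin gene KIF26A reached 19.3 ± 1.12, 19.1 ± 1.12 and 26.1 ± 6.74 CPM.

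The largest falls from K562 to edit-3 included MGST1, from 38.9 ± 2.8 to 0.0748 ± 0.060 CPM (log2 fold change -8.96, SE 0.25, adjusted p = 1.8e-12). ADGRA3 and the GABA receptor gene GABRA2, both on chromosome 4, had 0 reads in edit-3 and were at least 384-fold and 308-fold lower. HIST1H3F and HIST1H2BH had log2 fold changes of -9.55 and -9.37. KCNMA1 fell to 0.0673 ± 0.059 CPM, and ZPLD1, ZFAND4 and IGSF11 had 1 read each in edit-3.

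The histones were lower as a set, with 4 of 35 higher, 25 lower and 6 not passing (4 and 26 when adjusted over the list alone, median -0.69, camera adjusted p = 1.2e-13, adjusted p = 0.36 with an estimated correlation). HIST1H4D and HIST1H2BL fell by 1.75 and 1.71. A run of 19 genes at 26.03 to 26.39 Mb of chromosome 6, found by their shared shift, had a median of -0.70 and holds HIST1H3F. The run and the list share genes, so they are not separate results. A regional loss was not tested in this comparison. Of the 6 abundant RNAs without poly(A) tails, none was higher and 1 lower, with a median log2 fold change of -0.45 (0 and 0 when adjusted over the list alone, camera adjusted p = 0.67). Interferon response genes were higher, with 13 of 22 higher, 4 lower and 5 not passing, also when adjusted over the list alone (camera adjusted p = 3.9e-05, adjusted p = 0.30 with an estimated correlation). IFITM3, OAS3, TAP1 and the ubiquitin-like ISG15 rose by 3.65, 3.72, 3.71 and 1.83. Of 13 antigen presentation genes, 8 were higher, none lower and 5 not passing, also when adjusted over the list alone (camera adjusted p = 9.2e-06, adjusted p = 0.065 with an estimated correlation). The interferon and antigen presentation lists share members, so here too their calls are not fully separate. HLA-C rose from 0.101 ± 0.096 to 18.4 ± 2.12 CPM and PSMB9 from 0.133 ± 0.096 to 3.06 ± 1.18 CPM, and HLA-B went from 3 reads to 2.76 ± 0.33 CPM (ratio 104, interval 35.1 to 505, fitted log2 fold change 6.49 and 7.48 without K562 replicate 4).

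Glutathione genes and other NRF2 targets were lower, with 5 of 33 higher, 13 lower and 15 not passing, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.0021, adjusted p = 0.065 with an estimated correlation). GSTP1, a glutathione transferase gene, had a log2 fold change of -1.05 and AKR1C3 of -2.13. Nuclear genes of oxidative phosphorylation were lower, with 3 of 57 higher, 19 lower and 35 not passing, also when adjusted over the list alone (median -0.094, camera adjusted p = 0.043, adjusted p = 0.93 with an estimated correlation). NDUFS8, NDUFV1 and NDUFA1 of complex I and UQCRC2 of complex III fell by 1.0, 0.86, 0.78 and 0.73. In this comparison, 83.1% of genes inside runs of shifted neighbours changed, against 37.7% of the searched genes outside. Whether the list members named in this paragraph lie in such runs was not examined, so a regional shift of single members stays open. Of 49 erythroid genes, 19 rose and 11 fell (21 and 11 when adjusted over the list alone, camera adjusted p = 0.38), with XK and GYPB higher by 3.64 and 3.79 and CA2 at a log2 fold change of -3.73. Of 9 drug efflux transporters, 4 rose and 2 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.74), with ABCA3, ABCC4 and ABCC3 higher by 0.76, 0.37 and 3.32 (3.99 without K562 replicate 4). Of 8 topoisomerases and tyrosyl-DNA phosphodiesterases, 2 rose and 2 fell (2 and 3 when adjusted over the list alone, camera adjusted p = 0.72). TDP1 and TOP1MT had log2 fold changes of 0.20 and 0.26 (adjusted p = 0.031 and 0.040), weak calls. TDP1 ended without edit-3 replicate 3 or 4 or K562 replicate 2 or 4 (highest adjusted p = 0.14), and TOP1MT without edit-3 replicate 1 or 3 or K562 replicate 2, 3 or 4 (highest adjusted p = 0.12). Both also ended without a filter (adjusted p = 0.15 and 0.055) and in fits of only these 2 lines (adjusted p = 0.089 and 0.077).

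Of 31 lists, 5 passed in edit-3 versus K562 and none with an estimated correlation, and the oxidative phosphorylation call also ended with the replicate block (adjusted p = 0.066) and without edit-3 replicate 2 or 4 or K562 replicate 1 or 3 (highest adjusted p = 0.12). Lists not described in a comparison did not pass in it, and the lowest camera adjusted p among all lists that did not pass was 0.060, 0.061 and 0.14 in the 3 comparisons.

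**Figure D3:**
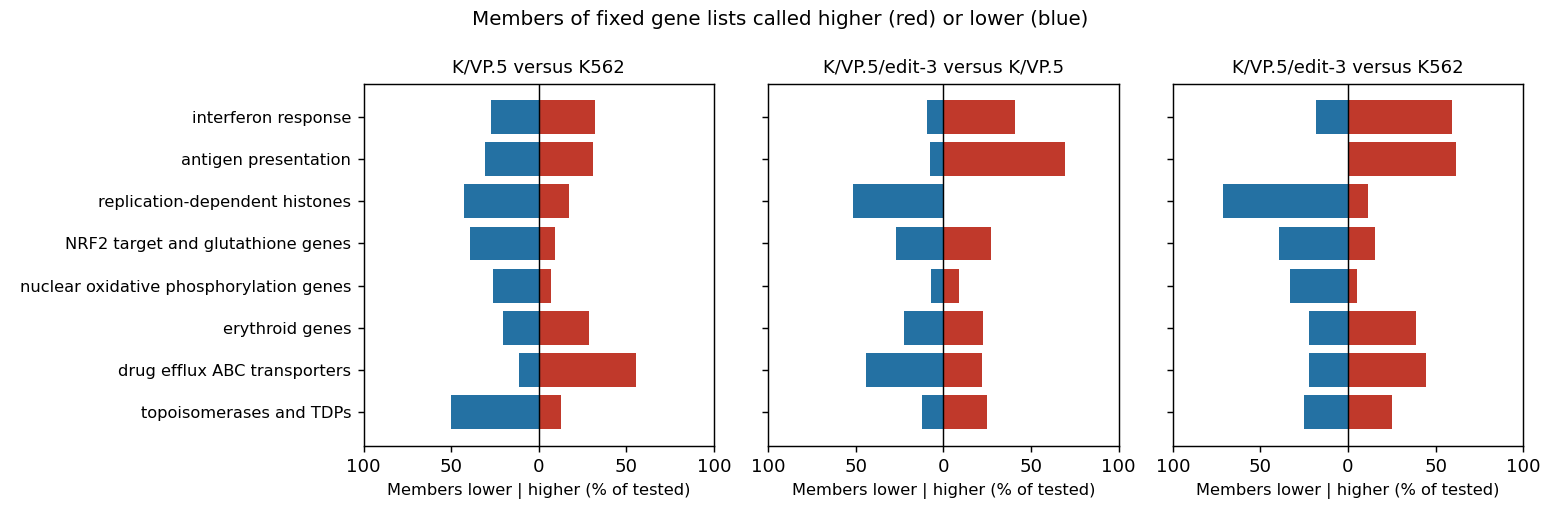
Share of the tested members of 8 gene lists fixed beforehand that were higher (red, to the right of 0) or lower (blue, to the left of 0) in each of the 3 comparisons, in percent of the members tested on both sides of the horizontal axis; TDPs are tyrosyl-DNA phosphodiesterases. Of the antigen presentation genes, 9 of 13 were higher in edit-3 than in K/VP.5, and of the histones 25 of 35 were lower in edit-3 than in K562.

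Changes of K/VP.5 were followed into edit-3. Of the 1500 genes at least 2-fold higher in K/VP.5 than in K562, 282 were at least 2-fold lower in edit-3 than in K/VP.5, where independent lists would share 47.7, and 173 were higher again, against 77.2. Of the 957 lower genes, 309 were higher in edit-3, against 49.2, and 64 lower again, against 30.4. Compared with K562, 1133 genes were higher in both sublines, against 151, and 475 lower in both, against 47.2. Among the 591 genes with opposite changes, 315 did not pass in edit-3 versus K562. TFAP2B, LINC01606, PKNOX2 and TLE4, a Groucho corepressor gene, rose in K/VP.5 and fell in edit-3. PKNOX2, a homeobox gene, had 0 reads in both K562 and edit-3 and 3.68 ± 0.26 CPM in K/VP.5, and TLE4 had 0 reads in K562, 4.12 ± 0.41 CPM in K/VP.5 and 0.0734 ± 0.031 CPM in edit-3. HAND2 fell in part, to 7.78 ± 1.54 CPM. The olfactory receptor gene OR51B2 did the opposite, with 2.72 ± 0.11 CPM in K562, 0 reads in K/VP.5 and 1.09 ± 0.32 CPM in edit-3. CENPIP1, ZC4H2, HIST1H3F and HIST1H2BH did not pass in edit-3 versus K/VP.5 (adjusted p = 0.47, 0.21, 0.82 and 0.62), with ZC4H2 at 5.31 ± 0.54 CPM in edit-3 and 4.27 ± 0.82 CPM in K/VP.5.

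The comparisons share libraries, which moves their signs together or apart without any effect. With the 4 K/VP.5 libraries split 2 and 2, 59.1% of the K/VP.5 changes had the opposite sign in edit-3 versus K/VP.5 (median of 6 splits, 56.8% to 60.6%), 52.4% of the higher and 69.7% of the lower genes. Without the split the share was 61.1%, and simulated unchanged groups, also without the split, gave 85.2%. With the K562 libraries split, 87.6% of the K/VP.5 changes had the same sign in edit-3 versus K562 (80.5% to 89.3%). Without the split it was 89.5%, and 85.3% in simulated unchanged groups without the split. No simulated value was computed for the split shares. The simulated values leave out real effects and the independent lists leave out the shared libraries, so the excess over either is not a measure of a shared effect.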

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

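The tests of neighbouring genes, of RNA from other blood cells, of single libraries, of the yield of RNAs without poly(A) tails, of the histone gene pair and of the other genes between the antigen presentation genes were chosen only after the results were seen. In 13 of 238 groups of 4 libraries, 1 library lay so far from the other 3 that its gap to the nearest exceeded Dixon's 95% critical value, and chance gives about 1 in 20. In K562, XK stood at 7.69 CPM in replicate 4 against 10.8 to 11.2, RN7SL2 at 8160 in replicate 1 against 9080 to 9200, RNU4-2 at 10.1 in replicate 2 against 5.34 to 5.94, and IFITM3 at 4.43 in replicate 4 against 3.6 to 3.72. In K/VP.5, replicate 4 stood apart for ABCG2 (2.69 CPM against 4.14 to 4.26) and GYPE (58.8 against 78 to 81.1). Replicate 2 of K/VP.5 stood apart for HIST1H4A (25.6 against 22.6 to 23), P2RY1 (5.49 against 6.22 to 6.37) and ANXA2 (161 against 140 to 143), and replicate 3 for RBFOX2 (69.4 against 60.9 to 61.4). In edit-3, ZC4H2 stood at 6.12 CPM in replicate 4 against 5.01 to 5.11, ZNF736 at 12.2 in replicate 2 against 8.59 to 9.08, and CA2 at 1.81 in replicate 1 against 2.99 to 3.14.

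Neighbouring genes shifted together in long runs, 27 in K/VP.5 versus K562 (1530 of 9764 genes) and 9 in edit-3 versus K/VP.5 (679 genes), where 100 shuffled gene orders gave at most 3 and 1. After removal of the trends with GC content and gene length, 97.6% and 95.4% of these genes were still in runs, which argues against such a bias. Fold changes of genes 50 places apart correlated at 0.10 and 0.067, above the highest shuffled values of 0.027 and 0.025, which argues against co-regulation of close neighbours alone. When runs were sought with every second gene, the genes left out were shifted the same way in 31 of 33 and 13 of 14 runs. Copy-number differences between the sublines remain a hypothesis that could account for the runs, and no DNA data were used here.

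Interferon response and antigen presentation genes were higher in edit-3 than in K/VP.5 (adjusted p = 0.11, no longer passing, and 0.036 with an estimated correlation). RNA from other blood cells is argued against, since 8 genes abundant in leukocytes, among them S100A9 and TYROBP at 0.0075 and 0 CPM in edit-3, had a median rise of -0.011 CPM where B2M rose by 78.1 CPM, although single blood cell genes rose, such as FCGR2A (14.7 to 104 CPM), MS4A3 (0.878 to 38.9) and CD3D (10.7 to 35.3). The highest camera adjusted p of the antigen presentation list over 9 fits without 1 library or with the within-line axis was 2e-05 at the preset correlation, which argues against a single library as its source there, while the estimated correlation was not rerun without each library. Of the interferon genes tested, only 2 lie on chromosome 6, and the 20 others passed camera at the preset correlation (adjusted p = 7.1e-05). This argues against a shift of chromosome 6 as the source of the call at that setting. The estimated correlation was not rerun without these members. For the antigen presentation genes, the 86 other coding genes between the members on chromosome 6 had a median log2 fold change of -0.013 (SE 0.059) against 1.10 for the members, which argues against a shift of the region, although the 5 members elsewhere did not pass as a set (adjusted p = 0.39), and no biological explanation was tested.

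Replication-dependent histones were lower in K/VP.5 versus K562 and in edit-3 versus K/VP.5 by camera, but not with an estimated correlation (adjusted p = 0.99 and 0.90), and the first call ended without HIST1H3F and HIST1H2BH (adjusted p = 0.17). In K/VP.5 versus K562, abundant RNAs without poly(A) tails had a median log2 fold change of -0.61 (SD 0.609) against -0.22 for the histones, so a lower yield of such RNAs stays open for the median of the list but not for the call that rests on this pair, and a regional loss cannot be told apart because 26 other genes among them had a median of 0.041 with an SE of 0.21. In edit-3 versus K/VP.5 these medians were 0.024 (SD 0.302) and 0.067 (SE 0.14) against -0.30 for all histones and -0.31 for those on chromosome 6, which argues against both. HIST1H3F and HIST1H2BH, 1046 bp apart with 0 annotated genes between them, changed by at least -9.73 in K/VP.5 where the lowest RNA without a poly(A) tail changed by -0.75, so yield does not account for the pair. At most 0.15% of their K562 level was left in edit-3, and a deletion that covers only this pair is a hypothesis that stays open.

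Each set of 8 libraries can be divided into 35 splits of 4 and 4. The real split was the 1 that gave at least 6688 genes in K/VP.5 versus K562 (highest other 1), 4309 in edit-3 versus K/VP.5 (highest other 1) and 7166 in edit-3 versus K562 (highest other 1339, with edit-3 replicate 1 and K562 replicates 1 to 3 against the rest, a count whose cause was not tested). At 2-fold or more, the real split was again the 1 with at least 2457, 1522 and 2739 genes. The highest other counts were 0, 1 and 312. Every other split mixes both lines in each group, which widens the spread within groups, so low counts there were likely beforehand. The counts were thus largest with the real labels, but these splits cannot exclude chance differences between cultures or clones. Among the 7 other splits that part all 4 pairs of K562 and K/VP.5 libraries, the highest count of genes was 0, and with the replicate block 7681 genes changed. Splits that part all pairs are too few for a share under 0.05. For the numbers of lists passing, 1, 3 and 5, as many came from 34, 34 and 30 of 35 splits (highest other 18, 20 and 20), so chance cannot be excluded for the list counts.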

How the results depend on the processing

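Beside the alternatives named here, the direction and side of the threshold held for the counts of genes, for TOP2A and for TOP2B. The block within 2 groups, the within-line axis, leaving out both libraries at its ends, and list tests without 1 library were chosen after seeing the data. With a stricter filter, 1617, 970 and 1809 genes changed at least 2-fold in K/VP.5 versus K562, edit-3 versus K/VP.5 and edit-3 versus K562, since fewer genes were tested. With an estimated correlation, 0, 1 and 0 lists passed. With the replicate block, 2 lists passed in K/VP.5 versus K562 and 7 in edit-3 versus K/VP.5, and 2 and 5 with the block in fits of 2 groups. With the axis as a covariate, 2 and 7 lists passed and 6587 genes changed in edit-3 versus K/VP.5, and without both libraries at its ends 8 lists passed there. The log2 fold change of TOP2A in edit-3 versus K/VP.5 was 0.196 without a filter, 0.199 in a fit of 2 groups and 0.198 with the block in it, all no longer past the test. The share of K/VP.5 changes opposite in edit-3 was 61.1% without the split, which shares libraries by construction. Leaving out 1 library gave 5839 to 6561, 3388 to 4765 and 6478 to 7553 genes in the 3 comparisons. The same fits gave 0.167 (without K/VP.5 replicate 4) to 0.25 (without edit-3 replicate 3) for TOP2A, and -0.00962 to 0.0575 for TOP2B, in edit-3 versus K/VP.5. TOP2B there was negative without edit-3 replicate 2 (-0.00962) or 4 (-0.00229) or K/VP.5 replicate 1 (-0.0082), and HIST1H3F, from -0.268 to 0.478, without edit-3 replicate 3 (-0.00882) or K/VP.5 replicate 4 (-0.268), none of them past the test in any fit. Lists passing ranged from 1 (without K562 replicate 2) to 3 (without K562 replicate 1) in K/VP.5 versus K562 and from 3 (without edit-3 replicate 2) to 6 (without edit-3 replicate 1) in edit-3 versus K/VP.5. Where no reason is given, the cause was not tested. Of the named genes other than TOP2A, calls ended for 3, 3 and 2 genes and were gained for 1 gene in each of the 3 comparisons. In edit-3 versus K562 the gained gene was TFAP2B, with 1 read in K562 and 6 in edit-3. It passed without K562 replicate 2 (log2 fold change 3.68, adjusted p = 0.04). Depth limits genes of a few reads, and 40109 of 58395 genes had too few reads to be tested.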

Other observations

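All tests of the runs of neighbouring genes and the choice of COL1A2, PEG10, SGCE and RUNX1 came after their values were seen. In K/VP.5 versus K562, 158 genes along chromosome 13 (19.96 to 114.3 Mb) had a median log2 fold change of 0.53, while 178 genes on 10q (80.45 to 133.4 Mb) had -0.57, 100 genes on chromosome 4 (0.4992 to 48.27 Mb) -0.59 and 92 genes on chromosome 17 (27.46 to 39.7 Mb) -0.52, a run that ends before TOP2A. In edit-3 versus K/VP.5, 160 genes on 14q (66.51 to 105.5 Mb) had 0.43, 120 genes on 3q (152.2 to 198 Mb) 0.46 and 99 genes on 12q (54.4 to 76.56 Mb) -0.51. With a limit of 0.4, genes in runs of edit-3 versus K/VP.5 were 426 instead of 679, and with a window of 41 genes there were 17 runs instead of 27 in K/VP.5 versus K562.

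COL1A2, a chain of type I collagen on 7q, rose in steps from 6.82 ± 1.66 CPM in K562 to 230 ± 31.4 in K/VP.5 and 2490 ± 558 in edit-3 (log2 fold changes 5.07 and 3.44, adjusted p = 2.8e-09 and 8.6e-08). PEG10, an imprinted gene of retrotransposon origin that lies close by, went from 7 reads over the 4 K562 libraries to 9.42 ± 1.22 CPM in K/VP.5 and 8.47 ± 2.17 CPM in edit-3 (log2 fold changes 7.15 and -0.16, adjusted p = 1.2e-09 and 0.65). SGCE, its imprinted neighbour, had 1 read in K562 and 0.363 ± 0.088 CPM in K/VP.5 (ratio 41.3, interval 7.06 to 1670, fitted log2 fold change 4.83 and 6.48 without K562 replicate 2). RUNX1, a transcription factor of blood cell development, stood at 46.1 ± 7.69 CPM in K562, 13.3 ± 0.89 CPM in K/VP.5 and 144 ± 23.1 CPM in edit-3.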
